A study of Mus musculus with 12 samples.

How the data were processed

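Poly(A) RNA of 12 pools of 10 mouse blastocysts was sequenced from libraries made with a SMART-Seq kit, in 6 groups of 2 libraries, per the labels. The processing information given with the samples names STAR 2.7.10, RSEM 1.2.28 and the genome build mm10, and no further settings. Each deposited table holds 1 library, with a row per gene and its RefSeq transcripts. Per the file headers the values are RSEM's expected count, TPM (transcript abundance scaled to library size), FPKM (fragments per kilobase, scaled to library size), and the length and effective length of each gene in bases. The expected counts were used for the tests and the TPM values for an alternative. The FPKM values were not used here, and the gap between length and effective length served as a measure of fragment size. Whether the libraries keep the strand is not given in the sources used here, so reads of overlapping antisense genes, such as Tsix and Xist, are not told apart with certainty. Of the expected counts 6.43% were not whole, and all were rounded to whole numbers.

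Genes with low counts were removed with edgeR's filterByExpr on the 6 groups with a minimum count of 10, which left 14743 of 24411 genes. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood tests, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All 12 libraries entered each fit. A model of the 6 group means gave the knockdown in ND, the knockdown in HFD, their difference (the interaction) and the diet effect in controls. An additive model of diet and treatment gave the knockdown over both diets, siNT against C, and diet over all treatments. Standard errors (SE) of log2 fold changes were derived from these fits. Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values are TMM-scaled. Nampt was also compared by exact two-sided permutation tests on log2 CPM, and its list of NAD synthesis was tested like the other lists.

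For the gene lists, 35 were fixed, of which 34 had at least 3 measured members. The list of genes encoded by mitochondrial DNA had 0 measured members. Lists were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 238 tests of lists and comparisons. The list tests of siNampt against C, added after the data were seen, are not among these and were adjusted among themselves alone. Medians are over the log2 fold changes of the members measured. Of the 238 tests 32 passed with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.929. The genes named in each comparison are Nampt, up to 3 members of smallest p from each list that passed, and genes from the 5 of smallest p where fewer than 5 passed, which are said not to pass and are not all given in the text. A part of the rule that names genes past the threshold found none. Genes called by other tools, and Nmrk1, Xist, Gm10052, Serpine2, Has2, Cyp19a1, Prm1 and Prm2 were named after their values were seen. These comparisons, tests, lists and the naming rule were fixed before the data were examined.

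The batch tag in the labels equals the replicate number in every group, so the numbers pair the libraries across groups. The pairing was checked by correlating the difference between replicates 1 and 2 across genes between groups. Over 15 pairs of groups r ranged from -0.06 to 0.22 with a median of 0.0917, and 6 were above 0.1. Between groups of the same diet r was 0.0917 to 0.22, and between groups of different diets it was -0.06 to 0.17. The replicate number was left out of the model and added as an alternative. Pairs of the same diet and batch are also given as counts.

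Depth was 42473129 to 50503064 expected counts per library. The median standard error of log2 fold changes, for genes with a mean of at least 5 CPM, was 0.225 for the knockdown within a diet, 0.318 for the interaction, 0.157 over both diets and 0.128 for diet over all treatments. The method was tested on simulated data with changes put into 100 genes at each size, or 99 for 4-fold changes by diet. In the knockdown in ND it recovered 22% of 2-fold and 60% of 4-fold changes. Over both diets it recovered 50% and 73%, and for diet over all treatments 55% and 83.8%, with 4, 9 and 8 false calls in the 3 comparisons. A list shifted by a known amount passed in each, and 0 other lists did. The simulated genes were drawn independently of each other and without batches, so that 0 does not cover lists whose members vary together. In the other splits of the real libraries a median of 6 lists passed for the knockdown over both diets and 5 for diet.

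The alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter of 5 CPM in at least 2 libraries, the replicate number in the model, limma on log2 TPM with a pseudocount of 1, leaving out each library, only the libraries compared, the controls as the reference, and an estimated correlation for the lists. A correction for GC content and transcript length, a covariate from the Y-linked genes, and each of these with the replicate number were chosen after seeing the data, as was the list test against the controls. The Y-linked mean was lower in siNampt than in siNT in 4 of 4 pairs. In the knockdown comparisons this covariate can therefore take up part of the treatment difference. GC content and gene positions came from an annotation of GRCm38, which gave a GC content for 99.5% of the tested genes. Where 1 library was left of a group, its spread is assumed to be that of the other groups. For the comparisons of 4 against 4 libraries all 35 splits were tested, and for diet 100 of 462 were drawn. The splits were compared by their number of genes at an unadjusted p under 0.05, since 0 genes passed the adjusted threshold. They were also compared by the p of each list and by the number of lists that passed. Correlations across the 12 libraries were tested with 100000 permutations, and 3 were computed.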

Results

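Poly(A) RNA was sequenced from 12 libraries of mouse blastocysts, each made from a pool of 10 embryos of wild-type ICR mice, an outbred stock. The embryos were produced by in vitro fertilization and cultured until 96 hpi. They fell into 6 groups of 2 libraries. The labels name 2 diets (ND and HFD, not spelled out there, while the series title names normal weight and obese mice) and 3 treatments. The treatments were a control (C), a non-targeting siRNA (siNT) and an siRNA against Nampt (siNampt), both given to zygotes by electroporation at 3 to 6 hpi. Whether the control zygotes were electroporated without an siRNA is not given in the sources used here. The replicate numbers 1 and 2 are the batch labels, so each group has 1 library per batch. The labels do not say whether the pools came from separate matings, so the p-values measure the spread between pools of embryos. Totals of expected counts lay between 42473129 and 50503064 per library, a 1.19-fold range, and 16473 to 17948 genes had a count in a library. Of 24411 genes, 14743 were counted deeply enough to be tested. Replicates of a group correlated at 0.964 to 0.972 on the log2 CPM scale across genes.

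The series asks about the role of Nampt, also called visfatin, in early embryos of normal weight and obese mice. Nampt is the rate-limiting enzyme that makes NAD from nicotinamide. It is a protein-coding gene on the + strand of chromosome 12, from 32819545 to 32853349 in GRCm38, the assembly also called mm10. In the ND groups, Nampt stood at 54.2 and 38.2 CPM in C, 74.6 and 49.4 CPM in siNT, and 53.9 and 37.7 CPM in siNampt (replicates 1 and 2). In the HFD groups it stood at 67.0 and 57.3 CPM in C, 61.3 and 66.0 CPM in siNT, and 50.3 and 44.0 CPM in siNampt. Over both diets the means were 62.8 CPM ± 10.5 in siNT, 46.5 CPM ± 7.11 in siNampt and 54.2 CPM ± 11.9 in C (SD, n = 4).

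Nampt was thus 25.9% lower in siNampt than in siNT on the mean log2 scale, a log2 difference of -0.43. It was lower in 4 of 4 pairs of the same diet and batch. The exact two-sided permutation test of the 8 libraries gave p = 0.0857, where the smallest possible value is 0.0286, and the paired exact test gave 0.125, the smallest that 4 pairs allow. Within batches the log2 difference was -0.38 in batch 1 and -0.49 in batch 2. The edgeR quasi-likelihood fit gave -0.43 (SE 0.17) with an adjusted p of 0.396 over all genes. Its estimates were -0.44 (SE 0.24) in ND and -0.43 (SE 0.24) in HFD, and the difference between the diets was 0.00 (SE 0.34, adjusted p = 1.00), with a range from -0.32 without ND_siNT replicate 1 to 0.28 without ND_siNampt replicate 1, and -0.38 with C as the reference. The ND estimate was -0.11 without ND_siNT replicate 1, -0.20 without ND_siNampt replicate 2, -0.70 without ND_siNT replicate 2 and -0.72 without ND_siNampt replicate 1. Without ND_siNT replicate 1 the estimate over both diets was -0.28. The GC and length correction and the covariate of Y-linked genes, both added after the data were seen, gave -0.25 and -0.16 over both diets. With the replicate number added, these 2 fits gave -0.25 and -0.35, and the latter gave -0.42 in ND and -0.43 in HFD. The covariate itself was lower in siNampt than in siNT, so it can take up part of the treatment difference. Against the controls the edgeR estimate was -0.01 in ND (adjusted p = 1.00) and -0.40 in HFD (adjusted p = 0.838). Over both diets Nampt in siNampt was 13.2% lower than in C (exact p = 0.343) and lower in 4 of 4 pairs (paired exact p = 0.125, the smallest possible), and in siNT it was 17.0% higher than in C (exact p = 0.371). The edgeR estimate of siNT against C was 0.22 (SE 0.17), and it was 0.08 without ND_siNT replicate 1, 0.09 without ND_C replicate 2 and 0.11 with limma on the TPM values. The difference in Nampt did not pass these tests. In the deposited TPM values the log2 difference between siNampt and siNT was -0.29 (exact p = 0.143).

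**Figure D1:**
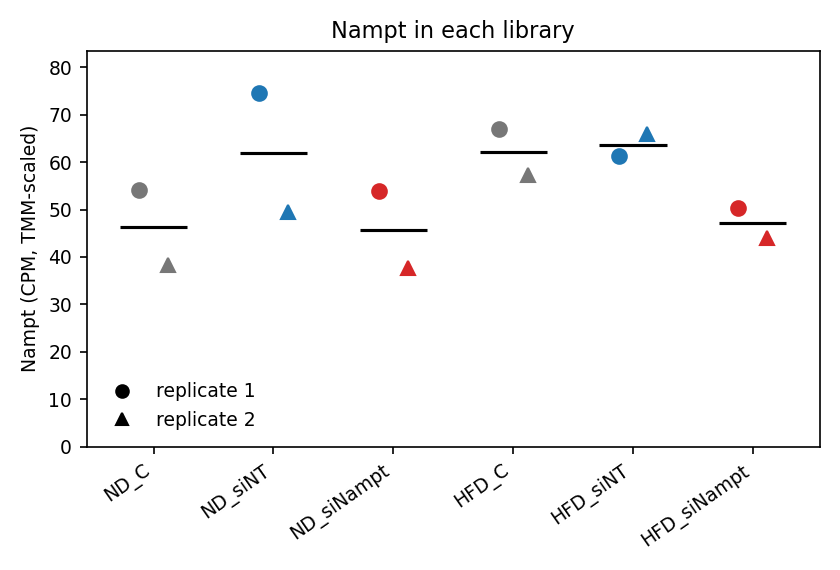
Nampt in each library, in TMM-scaled CPM, by group, with circles for replicate 1, triangles for replicate 2 and bars for the means of the 2 libraries. The siNampt libraries sit between 37.7 and 53.9 CPM and the siNT libraries between 49.4 and 74.6 CPM.

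The knockdown over both diets, siNampt against siNT with 4 libraries each, had lower levels of genes for the respiratory chain in siNampt. The nuclear-encoded genes of oxidative phosphorylation (OXPHOS), the mitochondrial complexes that make ATP, had a median log2 fold change of -0.25, and 62 of the 71 measured members were lower in siNampt. Ndufv2 and Ndufb4, subunits of complex I, were at -0.42 (SE 0.10) and -0.35 (SE 0.10), and Cox7c, a subunit of cytochrome c oxidase, at -0.43 (SE 0.13). With p-values adjusted over the list alone, 31 members were lower and 0 higher, while over all genes tested 0 passed. Ribosomal protein genes had a median of -0.19, with 79 of 84 lower, and Rps13 stood at -0.33 (SE 0.10). The list test, limma's camera with a preset correlation of 0.01, gave an adjusted p of 1.47e-18 for OXPHOS and 1.14e-15 for ribosomal proteins. With an estimated correlation neither call held (adjusted p = 0.929 for both).

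Against the controls these 2 lists differed little in siNampt over both diets. The OXPHOS median of siNampt minus C was -0.06 (adjusted p = 0.0286) and the ribosomal median was -0.02 (adjusted p = 0.373). By diet the ribosomal median against C was -0.10 in ND (adjusted p = 4.7e-06) and 0.05 in HFD (adjusted p = 0.0469). The siNT libraries, in turn, were above C in both lists, as given below, and the same 4 siNT libraries enter both comparisons. The OXPHOS list mean was lower in siNampt than in siNT in 4 of 4 pairs, by 0.37 log2 units in the pair of HFD replicate 2 and by 0.00 in that of HFD replicate 1. By batch, the list median was -0.14 in batch 1 and -0.34 in batch 2 for OXPHOS, and -0.13 and -0.26 for ribosomal proteins. A correction for GC content and transcript length, added after the data were seen, took the OXPHOS median to -0.06 (adjusted p = 5.5e-05) and the ribosomal median to -0.02 (adjusted p = 0.454), which ended the ribosomal call.

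Targets of p53, the tumour suppressor that responds to DNA damage, had a median of 0.27 with 21 of 25 higher in siNampt (adjusted p = 0.00646; 0.929 with an estimated correlation). Among them Btg2 stood at 0.69 (SE 0.22) and Aen at 0.56 (SE 0.19). This call was lost without ND_siNT replicate 1 (median 0.19) or ND_siNampt replicate 2 (median 0.13), and with the expression of sex-linked genes as a covariate, added after the data were seen, the median was -0.08 (adjusted p = 0.575). Against C the p53 median of siNampt was -0.06 (12 of 25 higher, adjusted p = 0.898). Genes of tight junctions and of blastocyst cavity formation had a median of 0.11 with 18 of 25 higher (adjusted p = 0.0320, and 0.929 with an estimated correlation), among them Cldn6 at 0.46 (SE 0.17) and Slc9a3r1 at 0.41 (SE 0.12). Against C their median in siNampt was 0.06 (20 of 25 higher, adjusted p = 0.0537). Their call against siNT was lost with the GC and length correction (median 0.08), and without ND_siNT replicate 2 (0.13), ND_siNampt replicate 1 (0.08) or HFD_siNT replicate 1 (0.12).

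No single gene passed the adjusted threshold of 0.05 in this comparison with edgeR or with limma on the TPM values. At an unadjusted p under 0.05 edgeR counted 1645 genes, 900 higher and 745 lower, where 737 are expected by chance. That count was 700 with the GC and length correction, 691 with the sex-linked covariate and 560 with C as the reference, and it ranged from 990 without ND_siNT replicate 1 to 2220 without HFD_siNampt replicate 1. DESeq2 called 1 gene, Gm10052, a predicted gene counted only in replicate 2 of siNampt (1.87 CPM in ND, 15.4 CPM in HFD), whose reads a near-identical copy could share. The 5 genes of smallest p, which did not pass, were Pvrl2 (0.66, SE 0.14), Ccdc92 (0.91, SE 0.21), Enthd2 (0.86, SE 0.20), Eps8l2 (0.67, SE 0.15) and Apobec1 (-1.66, SE 0.39), all with an adjusted p of 0.396. Without the filter on low counts edgeR called 119 genes, but in that fit the prior degrees of freedom of the spread were estimated as infinite, which sets aside the spread of each gene.

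**Figure D2:**
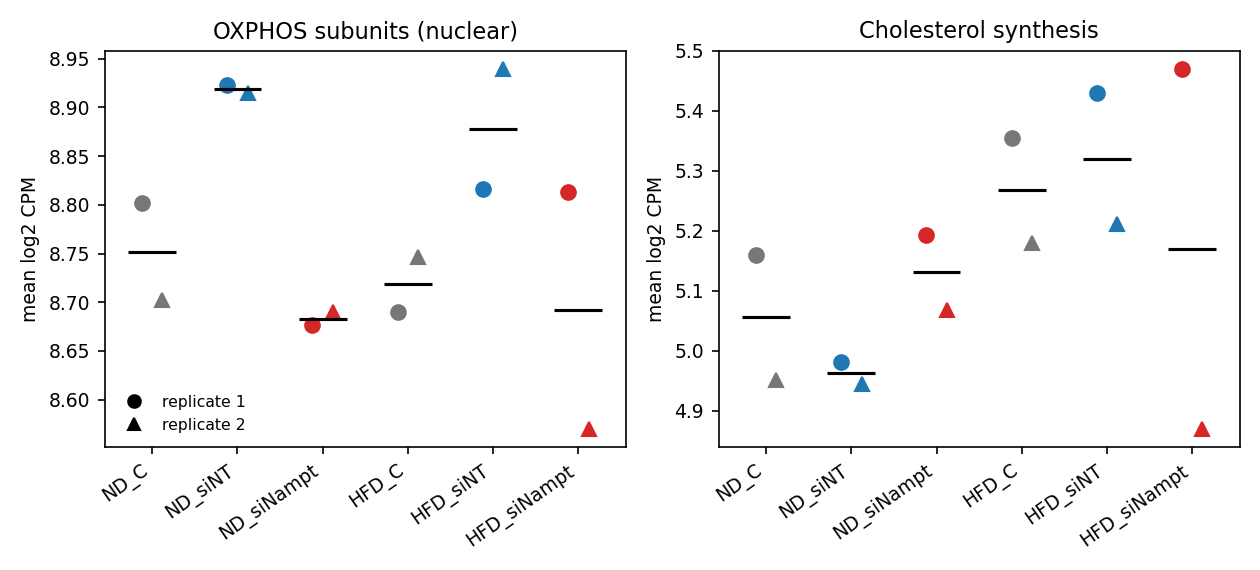
Mean log2 CPM of the 71 nuclear OXPHOS genes (left) and the 24 cholesterol synthesis genes (right) in each library, with circles for replicate 1, triangles for replicate 2 and bars for group means, on axes that do not start at 0. OXPHOS means were lower in siNampt than in siNT in 4 of 4 pairs, and cholesterol synthesis means were higher in HFD than in ND in 5 of 6 pairs.

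In the ND embryos alone, siNampt against siNT with 2 libraries each, the marker list of the trophectoderm, the outer epithelium of the blastocyst, had a median of 0.29 with 17 of 24 higher in siNampt (adjusted p = 0.0132; 0.929 with an estimated correlation). Among its keratins Krt19 was at 1.47 (SE 0.37), Krt18 at 0.63 (SE 0.18) and Krt8 at 0.49 (SE 0.13), and these 3 were the members under 0.05 with p-values adjusted over the list alone (0.0274, 0.0302 and 0.0274), while over all genes their adjusted p was 0.536 and none passed. Krt8 lies on chromosome 15 from 101996698 to 102004482 and stood at 1901 and 1863 CPM in ND_siNampt against 1341.8 and 1342.5 CPM in ND_siNT. Tight junction and cavity genes had a median of 0.25 with 17 of 25 higher (adjusted p = 0.0224; 0.929 with an estimated correlation), among them the claudins Cldn4 at 0.61 (SE 0.19) and Cldn6 at 0.68 (SE 0.25). Targets of p53 had a median of 0.47 with 20 of 25 higher (adjusted p = 0.000763; 0.929 with an estimated correlation). Phlda3 stood at 0.82 (SE 0.24) and the apoptosis effector Bax at 0.44 (SE 0.14). Against ND_C the median of ND_siNampt was 0.03 for p53 targets (adjusted p = 0.939), 0.22 for the trophectoderm list (adjusted p = 0.00242) and 0.13 for the tight junction list (adjusted p = 0.00865), and the OXPHOS median was -0.08 (53 of 71 lower, adjusted p = 0.0355). List tests of siNampt against C were run with the preset correlation alone.

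Ribosomal protein genes were lower in ND_siNampt with a median of -0.32, 82 of 84 members being lower (adjusted p = 1.57e-25), and OXPHOS genes had a median of -0.27 with 62 of 71 lower (adjusted p = 5.02e-13). With an estimated correlation the adjusted p was 0.929 for both. The GC and length correction took the medians to -0.09 (adjusted p = 0.000175) and -0.06 (adjusted p = 0.145), ending the OXPHOS call, and it also ended the calls of the trophectoderm (0.20) and tight junction lists (0.15). The trophectoderm call was lost without ND_siNT replicate 2 (0.27) or ND_siNampt replicate 1 (0.23). That of tight junctions was lost without ND_siNT replicate 1 (0.22), ND_siNT replicate 2 (0.17) or ND_siNampt replicate 1 (0.12). The p53 call was lost without ND_siNT replicate 1 (0.33) or ND_siNampt replicate 2 (0.03) and with the sex-linked covariate (0.05, adjusted p = 0.534), and ND_siNampt replicate 2 is also the library with few Y-linked transcripts in this group.

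In edgeR, DESeq2 and limma, 0 genes passed in the ND knockdown, and 1230 lay under an unadjusted p of 0.05 with edgeR, 679 higher and 551 lower. That count was 772 with the GC and length correction, 719 with the sex-linked covariate, 377 with C as the reference and 681 without ND_siNT replicate 2. The genes of smallest p, all at an adjusted p of 0.536, included Smad3, which carries TGF-beta signals, at 2.17 CPM ± 0.14 in siNampt against 5.53 CPM ± 0.03 in siNT (SD, n = 2; log2 -1.35, SE 0.28), Adprhl2, which removes ADP-ribose from proteins, at 10.8 CPM ± 3.09 against 4.24 CPM ± 0.22 (1.35, SE 0.27), and the actin-severing Scin at 1.502 CPM ± 0.498 against 0.27 CPM ± 0.08. Pde5a had 0 counts in siNampt against 47 in siNT, at least 18.8-fold lower with a floor of 3 counts over the group. Rnf8-cmtr1, which overlaps both genes it is named for, had 42 counts against 0, at least 11.7-fold higher by the same floor. In the 2 ND_C libraries Rnf8-cmtr1 had 24 and 21 counts, Scin 60 and 99 (13 and 9 in ND_siNT), and Adprhl2 339 and 292 (174 and 175 in ND_siNT). Smad3, in turn, had 270 and 218 counts in ND_C, near its 220 and 236 in ND_siNT and above its 99 and 116 in ND_siNampt. Pde5a had 20 and 10 counts in ND_C, 27 and 20 in ND_siNT and 0 in each ND_siNampt library.

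In the HFD embryos, siNampt against siNT with 2 libraries each, OXPHOS genes again had a lower median, at -0.22 with 63 of 71 lower (adjusted p = 1.56e-11; 0.929 with an estimated correlation). Atp5f1, a subunit of ATP synthase, stood at -0.40 (SE 0.15) and Cox6b1 at -0.35 (SE 0.14). The call was lost without HFD_siNampt replicate 2 (median -0.04), and by batch the median was 0.00 in batch 1 and -0.46 in batch 2. Against HFD_C the OXPHOS median of HFD_siNampt was -0.04 (39 of 71 lower, adjusted p = 0.379). Ribosomal protein genes had a median of -0.15 in batch 2 and 0.05 in batch 1. Of single genes, 0 passed in edgeR or limma, with 630 at an unadjusted p under 0.05 (264 without HFD_siNT replicate 2, 1242 without HFD_siNampt replicate 1, 368 with the GC and length correction), while DESeq2 called 2, Gm10052 and Tmem254c, both with near-identical copies. With C as the reference edgeR counted 833 genes at an unadjusted p under 0.05, more than against siNT. The genes of smallest p in edgeR against siNT, at an adjusted p of 0.923, included Mospd1 at 114 CPM ± 6.47 in siNampt against 182 CPM ± 19.02 in siNT (SD, n = 2), and Esco1, an acetyltransferase of cohesin, at 51.7 CPM ± 0.82 against 85.7 CPM ± 0.96. Tmem254c was at 5.92 CPM ± 2.01 against 16.8 CPM ± 0.81. Galnt16 had 41 counts in siNampt and 0 in siNT, at least 13.3-fold higher with a floor of 3 counts over the group. In the 2 HFD_C libraries Galnt16 had 4 and 1 counts. Mospd1 had 8905 and 8026 counts in HFD_C, 8138 and 8357 in HFD_siNT and 5556 and 5145 in HFD_siNampt. Esco1 had 4609 and 3340 in HFD_C, 4172 and 3636 in HFD_siNT and 2389 and 2451 in HFD_siNampt. Tmem254c had 351 and 590 in HFD_C, 785 and 744 in HFD_siNT and 343 and 211 in HFD_siNampt.

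Whether the knockdown response differed between the diets was tested as an interaction, the HFD response minus the ND response. For 5 lists this difference passed with the preset correlation. Ribosomal protein genes differed by a median of 0.25 (80 of 84 above 0, adjusted p = 1.19e-15, 0.929 with an estimated correlation), being lower under siNampt in ND. Trophectoderm markers differed by -0.34 (18 of 24 below 0, adjusted p = 0.00362, 0.929 with an estimated correlation), with Krt19 at -1.34 (SE 0.52), Lgals3 at -1.31 (SE 0.49) and Krt7 at -0.91 (SE 0.43). Markers of the inner cell mass, the cells that form the embryo proper, differed by 0.18 (17 of 24 above 0, adjusted p = 0.0313, 0.929 with an estimated correlation), with the pluripotency factors Sox2 at 1.24 (SE 0.54) and Esrrb at 1.28 (SE 0.60). Cholesterol synthesis genes differed by -0.35 (15 of 24 below 0, adjusted p = 0.00103, 0.929 with an estimated correlation), with Acat2 at -0.64 (SE 0.25) and Idi1 at -0.76 (SE 0.38). Genes of the ATF4 response, which cells raise when amino acids run short or proteins misfold, differed by -0.65 (24 of 28 below 0, adjusted p = 0.00959, 0.929 with an estimated correlation).

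With C in place of siNT the interaction median was -0.02 for cholesterol synthesis (12 of 24 above 0, adjusted p = 0.0845), -0.43 for the ATF4 list (adjusted p = 0.221), 0.21 for ribosomal proteins (adjusted p = 4.7e-06), -0.24 for trophectoderm markers (adjusted p = 0.0469) and 0.37 for inner cell mass markers (adjusted p = 0.00865). The ribosomal call held without any 1 of the 8 libraries, and the GC and length correction took its median to 0.14 (adjusted p = 2.9e-06). That of the ATF4 list was lost without ND_siNT replicate 2 (-0.39), HFD_siNT replicate 2 (-0.40) or HFD_siNampt replicate 1 (-0.65), and without ND_siNampt replicate 1 the median was above 0 (0.13). Trophectoderm lost its call without ND_siNampt replicate 1 (-0.15) or HFD_siNampt replicate 2 (-0.29), and cholesterol synthesis without HFD_siNT replicate 1 (-0.23) or HFD_siNampt replicate 2 (-0.11). The inner cell mass list lost it without ND_siNT replicate 1 (0.18), ND_siNampt replicate 2 (0.26), HFD_siNT replicate 2 (0.29) or HFD_siNampt replicate 2 (0.01). Of single genes, 0 passed in edgeR, DESeq2 or limma, and 451 lay under an unadjusted p of 0.05 in edgeR (299 without ND_siNT replicate 2, 1132 without HFD_siNampt replicate 2). With C as the reference 620 genes lay under that unadjusted p. The genes of smallest p against siNT, at an adjusted p of 1.00, included Myd88 (-1.49, SE 0.33), the adaptor of Toll-like receptors, and Smad3 (1.71, SE 0.39). The fibronectin gene Fn1 (1.06, SE 0.27) and Cers2 (-0.80, SE 0.21), a ceramide synthase, were also among them.

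The non-targeting siRNA was compared with the control embryos, 4 libraries each, as the background of an siRNA without a target, together with electroporation if the controls had none. OXPHOS genes were higher in siNT with a median of 0.19 (63 of 71 higher, adjusted p = 3.5e-18) and ribosomal protein genes with a median of 0.15 (81 of 84 higher, adjusted p = 1.12e-18). With an estimated correlation the adjusted p was 0.929 for both lists. The OXPHOS list mean was higher in 4 of 4 pairs, as was the ribosomal one. Ndufa3 and Uqcrq stood at 0.30 (SE 0.10) and 0.31 (SE 0.10), and Rps25 at 0.24 (SE 0.08). Targets of p53 were lower with a median of -0.18 (23 of 25 lower, adjusted p = 0.000663, 0.929 with an estimated correlation), among them Plk2 at -0.92 (SE 0.29) and Btg2 at -0.53 (SE 0.22). DNA repair genes had a median of -0.13 (22 of 25 lower, adjusted p = 0.0164, 0.929 with an estimated correlation), with Brca1 at -0.33 (SE 0.14). Fatty acid oxidation genes had a median of -0.17 (20 of 26 lower, adjusted p = 0.0305, 0.929 with an estimated correlation), with Hadha, which runs several steps of beta-oxidation, at -0.40 (SE 0.12) and Acadl at -0.33 (SE 0.11).

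Genes of the ATF4 response had a median of 0.24 in siNT against C (19 of 28 higher, adjusted p = 0.0320, 0.938 with an estimated correlation), with the stress factor Ddit3 at 0.75 (SE 0.32) and the asparagine synthetase gene Asns at 0.55 (SE 0.25). Cell cycle genes had a median of -0.11 (24 of 33 lower, adjusted p = 0.0367; Bub1b at -0.45, SE 0.15) and genes of lysosomes and autophagy -0.09 (22 of 26 lower, adjusted p = 0.0376; Ctsd at -0.46, SE 0.15). With an estimated correlation the adjusted p was 0.929 for both of these lists. The GC and length correction took OXPHOS to 0.03 (adjusted p = 0.0887) and ribosomal proteins to 0.01 (adjusted p = 0.320) and also ended the cell cycle (-0.07) and lysosome calls (-0.08). Of the 8 calls only those of OXPHOS and ribosomal proteins held without any single library. The p53 call was lost without ND_C replicate 2 (-0.13) or ND_siNT replicate 1 (-0.09), that of DNA repair without ND_C replicate 1 (-0.11), HFD_C replicate 1 (-0.14) or HFD_siNT replicate 1 (-0.13), and that of fatty acid oxidation without ND_siNT replicate 2 (-0.11), HFD_C replicate 2 (-0.10) or HFD_siNT replicate 1 (-0.13). The ATF4 call was lost without ND_C replicate 2 (0.19), ND_siNT replicate 1 (0.16), HFD_C replicate 1 (0.14) or HFD_siNT replicate 2 (0.03), and with the sex-linked covariate (0.23, adjusted p = 0.0531). The cell cycle call was lost without ND_C replicate 2 (-0.08), ND_siNT replicate 1 (-0.08), HFD_C replicate 1 (-0.10), HFD_C replicate 2 (-0.07) or HFD_siNT replicate 1 (-0.11), and the lysosome call without any of 6 single libraries (-0.11 to -0.07), namely ND_C replicate 2, either ND_siNT library, either HFD_C library and HFD_siNT replicate 2. Against C the ATF4 list was also higher in siNampt, by a median of 0.32 over both diets (24 of 28 higher, adjusted p = 0.0151 with the preset correlation). That median was 0.44 in ND (26 of 28 higher) and 0.02 in HFD (17 of 28 higher). By pair, however, the list mean of siNampt was lower than that of C in 2 of 4, with differences from -0.39 to 0.87. In batch 1 it rose from C to siNampt (3.99 to 4.86 in ND, 3.26 to 4.02 in HFD). In batch 2 it fell (3.57 to 3.40 in ND, 4.36 to 3.97 in HFD). DNA repair genes were lower in siNampt than in C as well, with a median of -0.11 (18 of 25 lower, adjusted p = 0.0150). In siNT against C, genes that sense foreign RNA and respond to interferon did not pass, with a median of -0.06 over 16 members (adjusted p = 0.799).

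In the same comparison 0 genes passed in edgeR and limma, with 648 at an unadjusted p under 0.05 (365 without ND_C replicate 2, 1177 without HFD_C replicate 1), and DESeq2 called 2, Gm3139 and Gm3286, predicted genes of families with near-identical copies. In edgeR these 2 were among the 5 genes of smallest p, at 21.5 CPM ± 7.72 in siNT against 49.0 CPM ± 9.84 in C for Gm3139 and 8.26 CPM ± 4.42 against 23.3 CPM ± 13.6 for Gm3286 (SD, n = 4), with an adjusted p of 0.984. Klb, the co-receptor beta-klotho, was at 11.99 CPM ± 1.02 against 18.3 CPM ± 1.41, and Smpd1, the acid sphingomyelinase, at 73.6 CPM ± 15.4 against 102 CPM ± 13.4. Ifng had 1 count in siNT and 428 in C, a ratio of 0.0026 (95% exact binomial counting interval 6.6e-05 to 0.0146), with its counts in C all in the ND libraries.

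**Figure D3:**
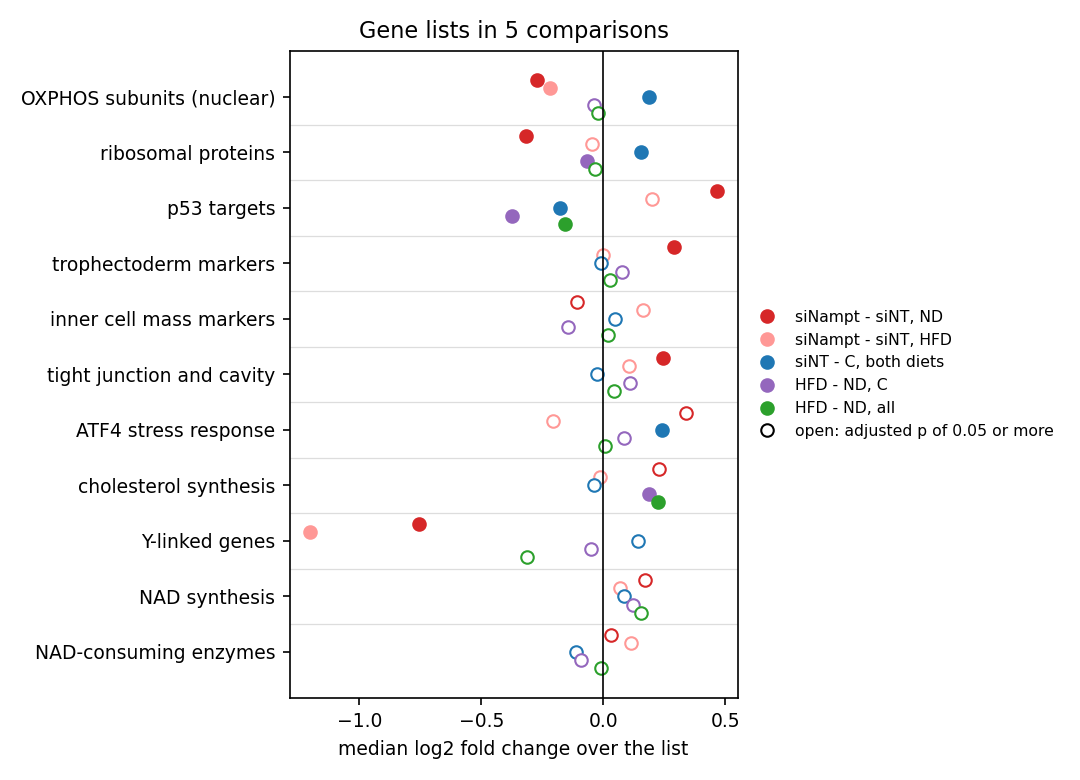
Median log2 fold change of 11 gene lists in 5 comparisons, filled where camera with a preset correlation gave an adjusted p under 0.05 and open otherwise. OXPHOS and ribosomal protein genes lie below 0 for siNampt against siNT in ND (-0.27 and -0.32) and above 0 for siNT against C (0.19 and 0.15), with 0 calls left with an estimated correlation.

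The effect of diet was asked over all treatments, HFD against ND with 6 libraries each, and in the controls with 2 each. The model over all treatments took the 6 libraries of a diet as independent. The differences between replicates were, however, correlated among the treatments of a diet (r = 0.0917 to 0.22). Its p-values and the fits that leave out 1 library may therefore overstate the support for a diet effect. Cholesterol synthesis genes were higher in HFD, with a median of 0.22 over all treatments and 21 of 24 members higher (adjusted p = 4.09e-06; 0.929 with an estimated correlation). Cyp51, the sterol demethylase on chromosome 5 from 4081145 to 4104746, was at 0.48 (SE 0.17), Fdps, the farnesyl diphosphate synthase, at 0.30 (SE 0.12), and Mvk, the mevalonate kinase, at 0.32 (SE 0.13). No member passed with p-values adjusted over the list alone. The list mean was higher in HFD in 5 of 6 pairs of the same treatment and batch, the exception being the siNampt pair of replicate 2, and the list median was 0.28 in batch 1 and 0.11 in batch 2. The call held without any 1 of the 12 libraries, with medians from 0.19 to 0.31.

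In the controls the same list had a median of 0.19 with 19 of 24 higher (adjusted p = 0.00393, 0.929 with an estimated correlation), a call lost without ND_C replicate 2 (0.08) or HFD_C replicate 1 (0.12). Idi1 stood at 0.54 (SE 0.27) there. Targets of p53 were lower in HFD, with a median of -0.16 over all treatments (19 of 25 lower, adjusted p = 0.0132) and -0.37 in the controls (23 of 25 lower, adjusted p = 0.00646). With an estimated correlation the adjusted p was 0.929 for both. Perp was at -0.41 (SE 0.17) and the cell cycle inhibitor Cdkn1a at -0.37 (SE 0.19) over all treatments, and by batch the list median was 0.09 in batch 1 and -0.34 in batch 2. The p53 call in the controls was lost without ND_C replicate 2 (-0.04) or HFD_C replicate 2 (-0.26), and that over all treatments without any of 5 single libraries (-0.14 to -0.05). Replication-dependent histone genes had a median of -0.60 in the controls (46 of 56 lower, adjusted p = 0.000108, 0.929 with an estimated correlation), which was lost with the stricter filter (-0.20, adjusted p = 0.953) and without HFD_C replicate 1 (-0.48). Their transcripts mostly lack a poly(A) tail. Ribosomal protein genes were at -0.07 in the controls (65 of 84 lower, adjusted p = 0.0224, 0.929 with an estimated correlation), at 0.02 with the GC and length correction, and without a call when ND_C replicate 1 (-0.03) or HFD_C replicate 2 (-0.05) was left out.

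Over all treatments, 0 genes passed for diet in edgeR or limma, and 474 lay under an unadjusted p of 0.05 in edgeR (342 to 758 with 1 library left out). DESeq2 called 2, Rbm45 and Csta1, which are also the genes of smallest p in edgeR. Rbm45, an RNA-binding protein gene on chromosome 2 from 76369984 to 76383768, was at 1.73 CPM ± 0.34 in HFD against 6.25 CPM ± 3.48 in ND (SD, n = 6), a log2 fold change of -1.82 (SE 0.31, adjusted p = 0.501). It passed in edgeR when ND_siNampt replicate 1 was left out (adjusted p = 0.00144), the ND library with its lowest level. Csta1, a cystatin gene with close paralogs, was at 65.3 CPM ± 20.03 against 35.7 CPM ± 11.6. The histone gene Hist1h4d was at 2.97 CPM ± 1.22 against 0.98 CPM ± 0.49, Magef1 at 3.06 CPM ± 0.78 against 5.61 CPM ± 1.98, and Rnf225 at 1.46 CPM ± 0.60 against 0.63 CPM ± 0.29.

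In the controls edgeR and limma called 0 genes for diet, with 414 at an unadjusted p under 0.05 in edgeR (284 without ND_C replicate 2, 753 without HFD_C replicate 2), and DESeq2 called 7 (Abcb5, Eif3j1, Gm4027, Guca1a, Ifng, Trim43b and Tspan7). With only the 4 control libraries in the fit, edgeR called 2, Eif3j1 and Gm4027. Gm4027 had 9 counts in HFD against 1955 in ND, at 0.09 CPM ± 0.04 against 19.7 CPM ± 17.2 (SD, n = 2), and Trim43b was at 5.38 CPM ± 2.53 against 22.0 CPM ± 11.5. Eif3j1, Gm4027 and Trim43b belong to families with near-identical copies, between which the counting could split reads. Ifng had 0 counts in HFD_C and 428 in ND_C, at least 141-fold lower in HFD_C with a floor of 3 counts over the group, and 353 of these counts were in ND_C replicate 2 and 75 in replicate 1. Acsl3, an acyl-CoA synthetase, was at 59.4 CPM ± 7.33 in HFD against 35.6 CPM ± 1.92 in ND, and Txnip, a thioredoxin-binding protein gene that responds to glucose, at 40.8 CPM ± 0.73 against 64.1 CPM ± 2.48, neither past the threshold (adjusted p = 1.00). Nampt did not pass for diet in the controls or over all treatments (smallest adjusted p 0.950). Its log2 fold change of HFD against ND in the controls lay between 0.29 and 0.44 across the main fit and 11 alternatives. With 1 library left out it ranged from 0.20 to 0.70. Over all treatments it lay between 0.13 and 0.23, and from 0.08 to 0.27 with 1 library left out. Floors and counting intervals cover counting error only.

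Sex-linked transcripts differed between pools. The 8 Y-linked genes together ranged from 68.04 CPM in HFD_siNampt replicate 2 to 429 CPM in ND_siNT replicate 2, a 6.30-fold range. Their mean was 168 CPM ± 128 in siNampt, 313 CPM ± 94.3 in siNT and 262 CPM ± 98.9 in C (SD, n = 4). The list was lower in siNampt than in siNT over both diets, with a median of -0.95 and 8 of 8 members lower (adjusted p = 3.26e-05; 0.929 with an estimated correlation). In ND its median was -0.76 (8 of 8 lower, adjusted p = 0.00392) and in HFD -1.20 (7 of 8 lower, adjusted p = 0.000366), and with an estimated correlation both had an adjusted p of 0.929. Against C the median of siNampt was -0.75 over both diets (8 of 8 lower, adjusted p = 8.7e-06), -1.45 in HFD (adjusted p = 0.000161) and -0.44 in ND, where it did not pass (6 of 8 lower, adjusted p = 0.0609). Ddx3y, which encodes an RNA helicase, stood at -0.99 (SE 0.42) over both diets. Both calls within a diet were lost without replicate 2 of siNampt, with a median of -0.19 in ND without ND_siNampt replicate 2 and -0.73 in HFD without HFD_siNampt replicate 2. They were also lost without ND_siNT replicate 2 (-0.54) and without HFD_siNT replicate 1 (-0.87). By batch the median over both diets was -0.43 in batch 1 and -1.88 in batch 2, and in ND alone it was 0.11 in batch 1. With the sex-linked covariate the median over both diets was 0.16 (adjusted p = 0.716), and with the stricter filter the call in ND was lost (-0.76, adjusted p = 0.0645). Xist, the RNA that silences an X chromosome in female cells, ranged from 32.4 CPM in ND_siNampt replicate 1 to 187 CPM in ND_C replicate 2.

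**Figure D4:**
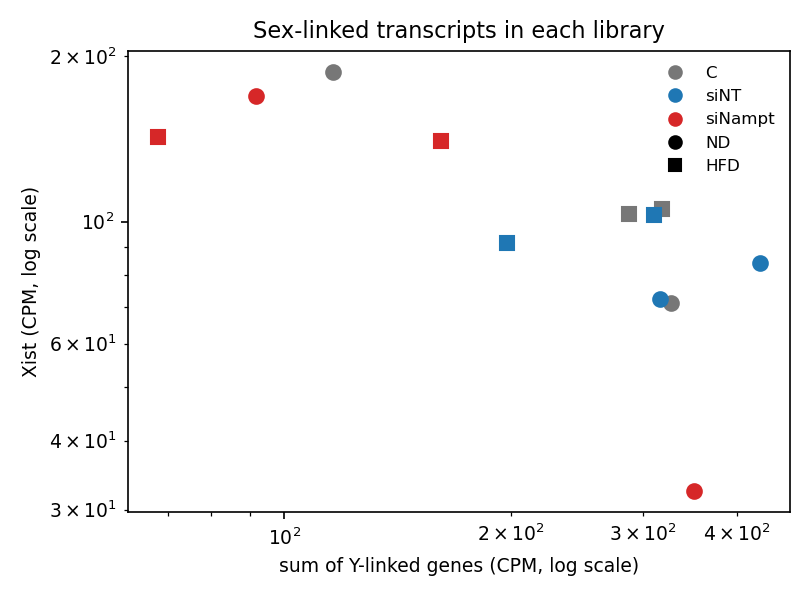
Sum of the 8 Y-linked genes (horizontal axis) against Xist (vertical axis) in each library, both in CPM on log scales, with circles for ND, squares for HFD and colours for the treatments. The library with the lowest Y-linked sum (68.04 CPM) has 143 CPM of Xist, and the one with the highest (429 CPM) has 83.9 CPM.

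Genes of NAD metabolism, the pathway of the targeted enzyme, did not pass in any of the 7 comparisons. The 18 measured genes of NAD synthesis had list medians between -0.09 and 0.17 (smallest adjusted p 0.233), and the 22 measured NAD-consuming enzymes, sirtuins and PARPs among them, between -0.11 and 0.15 (smallest adjusted p 0.308). Nmrk1, a kinase of nicotinamide riboside on a route to NAD, stood at 41.3 CPM ± 3.43 in ND_siNT and 39.2 CPM ± 4.20 in ND_siNampt. It stood at 50.1 CPM ± 2.00 in HFD_siNT and 38.3 CPM ± 1.08 in HFD_siNampt (SD, n = 2). It did not pass in edgeR (adjusted p = 0.928 in ND and 0.923 in HFD). Lists of insulin, IGF and adipokine signalling (smallest adjusted p 0.0669), glycolysis (0.182), the TCA cycle (0.0537), lipid synthesis and droplets (0.109), the antioxidant response (0.7097), apoptosis (0.170) and imprinted genes (0.296) passed in none of the 7 comparisons. Nor did those of the primitive endoderm (0.122), oocyte transcripts (0.114), the 2-cell stage (0.291), heat shock (0.344), the unfolded protein response (0.0573), hypoxia (0.637), chromatin and DNA methylation (0.296) and X inactivation (0.197). Of the list of cumulus and granulosa cells, Serpine2, a protease inhibitor gene, had a mean of 203 CPM over the 12 libraries, Has2 reached 1.77 CPM in a library and Cyp19a1 0.12 CPM, and the sperm genes Prm1 and Prm2 were at no more than 0.29 and 0.59 CPM. The lists of cumulus cells (0.109) and sperm (0.445) did not pass. Some of these lists did pass in siNampt against C, with the preset correlation alone. The TCA cycle passed in HFD (median -0.09, adjusted p = 0.0302) and in the interaction with C as the reference (-0.13, 0.0253). So did the primitive endoderm in ND (-0.20, 0.0335) and in that interaction (0.36, 0.0246). Chromatin and DNA methylation passed in that interaction (0.31, 0.0286), and the 2-cell stage (-2.43, 0.0466) and X inactivation (-0.36, 0.0427) in ND.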

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

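The comparisons of siNampt with C for the lists, of Y-linked genes with Xist and of Y-linked genes with the first principal component were tests chosen only after the results were seen, as were the GC and length correction and the sex-linked covariate.

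HFD_siNT replicate 1 had a gap between length and effective length of 186 bases, far from the 214 to 218 of the other siNT libraries and from the 216 to 231 of the other HFD libraries. ND_siNT replicate 2 had counts for 17636 genes, far from the 16473 to 16744 of the other ND libraries. Of 45 checks for a library far from the others 3 stood out, where chance gives about 1 in 20, or 2.25. The knockdown response differed between the diets in 5 lists, by 0.25 for ribosomal proteins, -0.34 for trophectoderm markers, -0.35 for cholesterol synthesis, -0.65 for the ATF4 response and 0.18 for inner cell mass markers (HFD minus ND).

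OXPHOS and ribosomal protein genes were lower in siNampt than in siNT. Library bias by transcript length, GC content and expression level could account for the ribosomal median, since 68.5% of 2000 random lists matched on these had one as low, and for much of the OXPHOS median, since 0% of matched lists reached -0.25 but their median was -0.17. Only the tested list was kept out of the matched lists. OXPHOS genes could thus be drawn for ribosomal genes and the reverse, so the matched medians may hold part of the pattern itself. The siNT libraries standing apart from C and siNampt alike is a candidate explanation for both lists, with siNampt minus C medians of -0.055 and -0.021. The ribosomal value joins opposite shifts, -0.10 in ND (77 of 84 lower) and 0.05 in HFD (57 of 84 higher). In ND the siNampt libraries were thus also below C. The level of Nampt itself cannot be told apart from chance with 12 libraries (r = 0.547, permutation p = 0.0666; rho = 0.524, p = 0.0841; r = 0.489 without the 2 farthest; 0.369 and 0.667 within batches 1 and 2; adjusted p = 0.0666 over 3 correlations). For the grouping, 1 of 35 splits gave an OXPHOS p as small, the real one (1.85e-20; best other 8.45e-19), but only 8 splits part all 4 pairs, too few for a share under 0.05, while 2 of 35 did for ribosomal proteins (2.39e-17; best other 1.89e-20), where chance cannot be excluded.

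Y-linked genes were lower in siNampt than in siNT. Fewer male embryos among those pooled may account for this, since Xist was higher where Y-linked genes were lower over the 12 libraries (r = -0.72, permutation p = 0.00705; rho = -0.83, p = 0.00168; r = -0.70 without the 2 farthest; -0.66 and -0.83 within batches 1 and 2; adjusted p = 0.0211). The Y-linked sum varied by 46.9% between libraries (CV), where drawing 10 embryos with a male share of 50% gives 31.6%. A list p as small came from 3 of 35 splits (1.37e-06; best other 6.1e-13), so chance cannot be excluded. Whether siNampt changed the survival of male embryos was not tested, as the sex of single embryos is not given in the sources used here.

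Cholesterol synthesis genes were higher in HFD than in ND. Library bias by transcript length, GC content and expression level is argued against, since 0% of 2000 matched lists had a median as high (0.22 against at most 0.0840). A difference in 1 batch alone cannot be told apart from a weaker one in both, as the lower of the 2 batch medians was 0.11 and the other 0.28, while in C alone they were 0.19 in batch 1 and 0.25 in batch 2, and the list mean of the siNampt pair of batch 2 differed by -0.20. A list p as small came from 11 of 100 splits (1.55e-07; best other 2.49e-13), so chance cannot be excluded, and the 5 drawn splits that part all 6 pairs are too few for a share under 0.05. The diet of the parents stays an open, untested explanation.

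Among genes at an unadjusted p under 0.05, the knockdown over both diets had 1645, and 3 of 35 splits had as many (highest other 1763), so chance cannot be excluded. Of the 8 splits that part all 4 pairs 2 had as many, and the split by batch had 904. For siNT against C the count was 648, with 12 of 35 splits as large (highest other 1465; 814 by batch), and for diet 474, with 73 of 100 (highest other 1679), so chance cannot be excluded for either. For diet the splits that part all 6 pairs reached 685, and the 1679 of a split that parts fewer points to a structure of the libraries, which was not tested. By lists past the threshold, adjusted within each comparison, the knockdown had 5, and 23 of 35 splits had as many (median of the others 6). For siNT against C there were 9 (5 of 35 splits as many, median 5), and for diet 2 (95 of 100, median 5). A list p as small came from 12 of 35 splits for p53 targets in the knockdown over both diets. It came from 18 of 35 for the ATF4 list in siNT against C, and from 42 of 100 for p53 targets by diet. Chance cannot be excluded for these.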

How the results depend on the processing

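The GC and length correction, the sex-linked covariate and each of these with the replicate number were tests chosen only after the results were seen. The edgeR counts of 0 genes held in all 7 comparisons with RLE size factors, the stricter filter, limma on TPM, the GC and length correction and the replicate number in the model. DESeq2 called 2 genes in the HFD knockdown, 1 over both diets, 2 for siNT against C, 7 for diet in the controls and 2 over all treatments. Without the filter the counts were 108 for the knockdown in ND, 68 in HFD, 40 for the interaction, 119 over both diets, 76 for siNT against C, 80 for diet in the controls and 99 over all treatments. The prior degrees of freedom were then infinite against 6.31 and 6.64 with the filter, and all but 1 of these genes pass the filter. With only the control libraries 2 genes passed for diet. The sex-linked covariate gave 2 genes in the HFD knockdown, and with the replicate number 1 in ND. For these the cause was not tested. Leaving out 1 library gave 0 to 1 genes for diet over all treatments, and 0 in the other 6 comparisons.

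Of the 32 list calls 0 held with an estimated correlation, 32 with RLE size factors, 30 with the stricter filter, 22 with the GC and length correction and 26 with the sex-linked covariate. The replicate block changed no other call. Of 216 fits that left out 1 library 152 kept the call, 63 lost it and 1 turned direction, the ATF4 interaction (-1.01 to 0.13). Ribosomal proteins for diet in the controls turned to 0.0187 with the GC and length correction and 0.0177 with the replicate number added. Y-linked genes turned to 0.16, 0.14 and 0.16 with the covariate (ND, HFD, both diets), as the covariate is made of them, and to -0.00478 (4 of 8 higher), 0.0729 and 0.275 with the replicate number added, and p53 targets over both diets turned to -0.0791. For the other reversals the cause was not tested. At this depth and number of libraries most 2-fold changes within a diet would be missed (22% recovered in simulated data).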

Other observations

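The relation of Y-linked genes to the first principal component was a test chosen only after the result was seen.

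Genes of the ATF4 response varied widely between libraries whatever their group. The list mean ranged over 1.60 log2 units, from 3.26 in HFD_C replicate 1 to 4.86 in ND_siNampt replicate 1. Trib3, a pseudokinase induced by ATF4, ranged from 1.63 to 28.2 CPM, Chac1, which degrades glutathione, from 0.13 to 19.3 CPM, and Asns from 135 to 433 CPM. Between the diets the list median was -0.50 in batch 1 and 0.60 in batch 2. Genes of the 2-cell stage, a family with near-identical copies, ranged over 3.25 log2 units in their list mean, highest in ND_C replicate 1 and lowest in ND_siNampt replicate 1.

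Eif3j1 stood at 34.97, 23.7, 11.6 and 7.23 CPM in 4 libraries (ND_C replicate 2, HFD_siNampt replicate 1, HFD_siNT replicate 1 and ND_C replicate 1) and at 0.03 CPM or less in the other libraries. The list means of oocyte transcripts and of NAD synthesis were higher in HFD than in ND in 6 of 6 pairs, by 0.01 to 0.59 and 0.01 to 0.51 log2 units, though neither list passed its test. Across all genes tested, which are not independent replicates, the log2 fold changes of the knockdown in ND and in HFD correlated at r = 0.0315 (Spearman rho = 0.176), and over the 8483 genes with a mean of at least 5 CPM at r = 0.314.

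The first principal component held 16.4% of the variance. The share of male embryos may go with it, as Y-linked genes and the component had r = -0.68 (permutation p = 0.0141) but rho = -0.45 (permutation p = 0.146), r = -0.42 without the 2 farthest libraries and -0.12 and -0.57 within batches 1 and 2, so the relation rests on those 2 libraries (adjusted p = 0.0211). The component also went in part with the batch. All batch 1 libraries lay between -29.0 and -15.5 on it. In batch 2, ND_C, ND_siNT, ND_siNampt and HFD_siNampt lay at 48.9, 21.1, 52.5 and 30.2, and HFD_C and HFD_siNT at -9.24 and -20.7. ND_siNT replicate 2, at 21.1, had the highest Y-linked sum (429 CPM). Batch and sex were not told apart by a test.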
